A study of Mus musculus with 5 samples.

How the data were processed

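RNA-seq was carried out on mouse liver in 5 libraries, 2 of livers carrying floxed Heg1 without Cre (controls) and 3 of livers carrying floxed Heg1 with a Cre recombinase driven by Lyve1 (knockouts). Per the labels, the mice were males of 6 weeks given a high-fat diet for 4 weeks. The series title speaks of hepatocytes whereas the labels give liver as the tissue, so the values are treated here as those of whole liver.

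The deposited values are FPKM (fragments scaled by transcript length and library size) per gene symbol, rounded to 2 decimals. Per the submitters' processing notes, the authors used HISAT2, StringTie and DESeq2 with the mm10 genome build. Those notes give neither versions nor the role of each tool, and whether the counting used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Of the 2 deposited tables, each with 33589 rows, all 33589 rows held identical values, and the table whose columns carried the described sample names was used. No column of another sample was present in either. Within it, 220 rows repeated an earlier symbol and were kept as rows of their own. Among the rows that passed the filter on mean FPKM, 135 held exactly the values of another row, as do the hemoglobin genes Hbb-b1 and Hbb-bs.

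FPKM are not counts, and the depth of the libraries is unknown. Low values were examined for steps of whole reads in genes with 1 exon of 150 to 900 nt and at least 0.1 FPKM. Only between 25.8% and 35.7% of those values, depending on the library, lay within 0.1 of a whole multiple of the most common small step, so whole reads were not recovered and no interval based on counts is given. FPKM sums were between 797692 and 820498 per library, and between 10614 and 10945 genes had at least 1 FPKM. Paralogs with near-identical sequence share reads, and the values of the major urinary protein (Mup), Xlr3, Ces1, Cyp4a, Hamp and hemoglobin genes are therefore uncertain member by member. FPKM divide out a fixed total, so a change in a few very abundant liver transcripts moves every other gene slightly. The 10 most abundant genes held between 26.1% and 28.7% of the summed FPKM.

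The main test was limma 3.58.1 in R 4.3.3, with a trended prior variance, on log2(FPKM + 1) of the 10820 genes with a mean FPKM of at least 1. Genotype was the only term, all 5 libraries entered 1 fit, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are differences of mean log2(FPKM + 1), knockout minus control, which understates the change of genes with low FPKM. Heg1 itself lay below the filter, as did the preset genes Klf4 and Wnt9b. They were fitted with a filter of 0.1 mean FPKM (14401 genes), which departs from the plan made for the other genes. Heg1 was also tested by an exact two-sided permutation over the 10 splits of the 5 libraries into 2 and 3. Groups were taken from the labels. The labels number the livers within each genotype and state neither litter nor batch, nor that each library comes from a separate animal, so SDs and p-values measure the spread between these libraries.

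Gene groups were 47 lists of pathway genes and cell type markers written before the data were examined. Of these, 39 had at least 5 tested members. Each was tested against all other genes with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 39 lists, and again with the correlation estimated from the data and with fry, limma's rotation test of the list alone. For each list the members were also adjusted over the list alone. Symbols were matched to older names through RefSeq and GENCODE symbols, with G6pc1 and Rigi renamed by hand (25 of 976 list entries), and 7 entries had no row. Gene positions and transcript lengths came from GENCODE M21 on GRCm38, the assembly also called mm10, where 30845 of the 33589 rows were found by symbol.

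The rule for the genes named in the text was also written beforehand. It takes, among genes with an official symbol and groups whose FPKM do not overlap, the 12 per direction with the largest fold change that passed, filled up with the smallest unadjusted p, together with Heg1, 14 preset genes and up to 4 members with the smallest p of each list described. A gene that the rule takes is not reported here, nor a test that needed it. Any other gene named is said to have been chosen after its values were seen.

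The gene test was tried on simulated data with the real means of the 10820 genes and their spreads after limma's shrinkage towards its prior. Noise was normal and independent between genes, unlike in real livers. With 200 genes changed, it recovered 87.7% of 2-fold, 98.9% of 4-fold and 99.8% of 8-fold changes. With 10 genes changed, it recovered 27.0% of 2-fold, 97.0% of 4-fold and 99.0% of 8-fold changes. In the real data Cyp4a14, with a log2 fold change of -4.05, did not pass (limma adjusted p = 0.587). These shares may therefore not hold for the real livers, and a lack of calls does not exclude large changes. With none changed it made 0.2 wrong calls per run. For 2-fold, 4-fold and 8-fold changes it made 13.4, 11 and 14.4 wrong calls per run with 200 genes changed. With 10 genes changed these were 0.7, 0.95 and 0.95. The list test found a simulated log2 shift of 0.5 in the cholesterol synthesis list in 20 of 20 runs. It made 5 wrong list calls over 20 runs of 39 unshifted lists with independent genes.

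Alternatives set beforehand were other pseudocounts, filters and scalings, limma without trend, robust or with library weights, the replicate number as a block, each library left out in turn, a fold-change threshold and the other table. A correction for transcript length was added after the data were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.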

Results

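The data are FPKM of liver RNA from male mice of 6 weeks fed a high-fat diet for 4 weeks, with 5 libraries in all. In 2 control livers the Heg1 gene was floxed and no Cre was present. In 3 knockout livers the same floxed gene was combined with Lyve1-Cre, which acts in lymphatic and liver sinusoidal endothelial cells. HEG1 is a transmembrane receptor of endothelial cells that binds the CCM protein KRIT1. The design poses a single question, how the liver transcriptome on a high-fat diet differs when Heg1 is deleted in Lyve1-expressing cells. Group values below are mean FPKM ± SD over 2 control or 3 knockout livers. Sequencing depth is unknown, since FPKM carry no totals.

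The targeted gene was examined first. Heg1 (ENSMUSG00000075254.12, protein coding, chromosome 16, 33684370 to 33771576 on the plus strand, mm10) had 0.48 and 0.35 FPKM in the control livers and 0.45, 0.43 and 0.50 FPKM in the knockout livers. The log2 fold change was 0.046 (SE 0.11, 95% interval -0.21 to 0.31), with a limma adjusted p of 0.934. The exact permutation p was 0.5 over 10 splits, of which the smallest possible is 0.1. Its sign was not stable, since it turned to -0.012 with quantile normalization, -0.0405 with length correction and -0.0199 without control 2. The floxed part of the gene is not given, endothelial cells are a minority of liver cells, and a whole-gene value in whole liver can therefore check the labels only weakly. Lyve1, the gene that drives the Cre (chromosome 7, 110850607 to 110863239, minus strand), had 8.13 ± 1.12 FPKM in controls and 7.24 ± 3.30 FPKM in knockouts. Its log2 fold change was -0.23 (SE 0.34), and 0.10 without knockout 1.

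Across the 10820 tested genes the knockout livers had lower Cyp4a14, a fatty acid hydroxylase induced through PPARα, and lower G6pc1, which encodes the catalytic subunit of glucose-6-phosphatase. They had higher Idi1 and other cholesterol synthesis genes, higher Mup genes, which encode the major urinary proteins, and higher Moxd1, a monooxygenase-like gene with male-biased expression in liver. None of these genes passed the test over all genes. With limma and Benjamini-Hochberg adjustment 0 genes were higher and 0 lower, and the smallest adjusted p was 0.587. At an unadjusted p below 0.05 there were 757 genes, against 541 expected by chance, 572 of them higher and 185 lower in knockouts. That split depended on scaling, with 310 higher and 362 lower after median-of-ratios scaling, 279 and 321 after quantile normalization, and 315 and 319 after correction for transcript length. The FPKM of the groups did not overlap for 2738 genes, 25.3% of those tested, where chance gives 20%. Without control 1, 1 gene passed, Hamp (adjusted p = 0.0076), which was chosen after its values were seen.

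**Figure D1:**
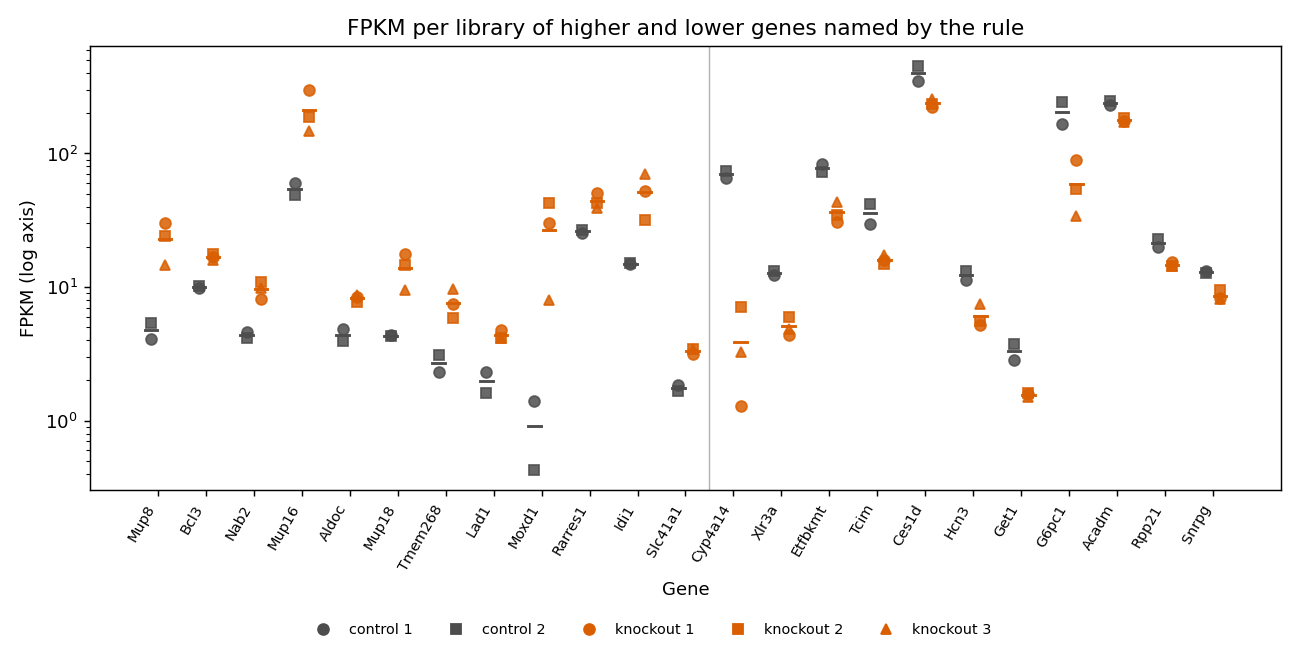
FPKM on a log axis of the genes named by the rule, each point 1 liver and each short bar the group mean, with controls in grey and knockouts in orange. By the rule, every knockout lies above both controls in the 12 genes at the left and below both in those at the right. Cyp4a14 has the widest gap among the lower ones.

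Among the 12 higher genes that the rule takes, 3 were Mup genes of the cluster on chromosome 4. Mup8 had 4.76 ± 0.92 FPKM in controls and 23.1 ± 7.92 in knockouts, Mup16 54.5 ± 7.81 and 212 ± 79.3, and Mup18 4.32 ± 0.057 and 13.9 ± 4.13. Tmem268, which lies on the same chromosome at 63558781 to 63586357, had 2.71 ± 0.54 and 7.66 ± 1.94 FPKM. Moxd1 (chromosome 10, 24223517 to 24302790) went from 0.92 ± 0.69 to 26.9 ± 17.5 FPKM, a log2 fold change of 3.63 (SE 0.64), with single knockouts at 30.1, 42.6 and 8.03. Idi1, the isopentenyl diphosphate isomerase of sterol synthesis, had 15.0 ± 0.25 and 51.3 ± 19.0 FPKM. Bcl3, a nuclear IκB protein, had 10.1 ± 0.30 and 16.8 ± 0.77. Nab2, a corepressor of EGR factors, had 4.41 ± 0.35 and 9.64 ± 1.37. The other 5 were Aldoc, Lad1, Rarres1, Slc41a1 and Tmem268 above, with log2 fold changes between 0.66 and 1.21. Each of the 12 was higher in 3 of 3 knockouts than in either control, which the rule requires. None passed the adjustment over all genes, with adjusted p of 0.587 or 0.675.

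Cyp4a14 (chromosome 4, 115486200 to 115496142) had the smallest p of all genes. It stood at 65.9 and 74.0 FPKM in controls and at 1.28, 7.06 and 3.25 FPKM in knockouts, a log2 fold change of -4.05 (SE 0.47, 95% interval -5.19 to -2.91). Xlr3a, 1 of a set of near-identical genes on the X chromosome, had 12.7 ± 0.61 and 5.08 ± 0.82 FPKM. Etfbkmt, a methyltransferase acting on the electron transfer flavoprotein, had 77.6 ± 7.50 and 36.4 ± 6.52 FPKM. Tcim had 35.9 ± 8.80 and 16.0 ± 1.24. G6pc1 had 206 ± 55.2 and 59.0 ± 27.9 FPKM. Acadm, the medium-chain acyl-CoA dehydrogenase, had 239 ± 9.87 and 177 ± 5.85 FPKM. Ces1d, Hcn3, Get1, Rpp21 and Snrpg were also lower in all 3 knockouts, with log2 fold changes between -0.92 and -0.51. These lower genes lay in 3 of 3 knockouts below either control, which the rule requires, and their adjusted p was 0.587 or 0.675 as well.

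The list of cholesterol synthesis and uptake genes, targets of SREBP2, was higher in knockout liver. Of its 25 members 24 were higher and 13 had groups that did not overlap, with a median log2 fold change of 0.54. Adjusted over the list alone 5 members rose, while 0 passed over all genes. These were Idi1, Dhcr7 (21.7 ± 0.50 and 36.2 ± 5.33 FPKM), Nsdhl (10.9 ± 0.27 and 24.0 ± 6.39 FPKM), Sqle (7.00 ± 1.12 and 18.0 ± 5.80 FPKM) and Srebf2 (8.85 ± 0.18 and 12.02 ± 0.56 FPKM). Relative to the mean of the 5 livers, the list stood at -0.51 and -0.22 in controls and at 0.33, -0.15 and 0.55 in knockouts, so knockout 2 lay near control 2. Camera with the preset correlation gave an adjusted p of 9.43e-10. The call was lost with an estimated correlation (adjusted p = 0.517). That version of camera rests on the few residual degrees of freedom of 5 libraries, and its p rose also in lists with an estimated correlation near 0. Wrong groupings of the livers, tried after the result was seen, gave smaller adjusted p in camera with the preset correlation. It was 4.61e-14 with control 1 and knockout 2 set as controls, and 1.68e-24 with knockouts 1 and 3 set as controls. A small adjusted p of this kind is therefore no measure of evidence for genotype.

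Mup genes were higher in the knockout livers in all 15 tested members of their list, which did not hold Mup8, Mup16 or Mup18. The median log2 fold change was 0.75, the preset-correlation adjusted p 6.85e-09, and the adjusted p = 0.517 with an estimated correlation. Among the 10 splits of the livers, looked at after the result was seen, the real one gave the Mup median furthest from 0. The next was -0.678, with knockouts 1 and 2 set as controls, and 10 splits are too few for a share under 0.05. Adjusted over the list alone 6 rose, among them Mup17 (204 ± 82.9 and 735 ± 237 FPKM), Mup15 (570 ± 95.1 and 2202 ± 943 FPKM), Mup9 and Mup14, and 0 passed over all genes. Summed over the family, Mup transcripts made up 29151 and 30222 FPKM in controls and 44092, 38417 and 38494 FPKM in knockouts. Male-biased liver genes were higher in 22 of 23 members (median 0.38, adjusted p = 3.53e-04, and adjusted p = 0.554 with an estimated correlation), with Moxd1 alone passing over the list and 0 over all genes. Examples were C6 (97.8 ± 13.6 and 161 ± 38.6 FPKM), Ugt2b1 (155 ± 7.57 and 202 ± 21.5 FPKM) and Cyp2u1. This list rested on control 2, where it was lowest, and was not called without control 2 (median 0.17, adjusted p = 0.356) or without knockout 1 (median 0.31, adjusted p = 0.05), and its median was 0.725 without control 1. The 9 female-biased members tested were lower in 8 cases (median -0.13, adjusted p = 0.0124, and adjusted p = 0.517 with an estimated correlation), with 0 passing over the list alone or over all genes. Cyp2b9 had 1.08 and 7.73 FPKM in controls and at most 0.23 in knockouts, and Cyp39a1 14.9 ± 0.18 and 10.2 ± 5.75 FPKM. The female-biased list was not called without control 2 (median -0.04, adjusted p = 0.436) and its median turned to 0.036 without knockout 1 (adjusted p = 0.249). It was -0.316 without control 1 and -0.451 without knockout 2.

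Genes of fatty acid oxidation and ketogenesis, targets of PPARα, were lower in 23 of 32 members (median -0.12, adjusted p = 3.38e-06, and adjusted p = 0.517 with an estimated correlation). Adjusted over the list alone, Cyp4a14, Acadm and Acaa1b (382 ± 26.1 and 263 ± 31.5 FPKM) fell, and 0 passed over all genes. Groups did not overlap for 12 members that were lower and for 4 that were higher. Vnn1 had 11.98 ± 1.53 and 8.35 ± 1.22 FPKM. This was the only list called by fry's mixed test, which asks whether members change in either direction (adjusted p = 0.0395). Drug metabolism genes driven by CAR and PXR were lower in 18 of 22 members (median -0.27, adjusted p = 1.63e-07, and adjusted p = 0.517 with an estimated correlation). Gstm1 (929 ± 71.0 and 679 ± 72.1 FPKM), Nr1i3, which encodes CAR itself (153 ± 0.92 and 105 ± 20.5 FPKM), and Ugt1a1 (258 ± 1.12 and 213 ± 13.6 FPKM) had groups that did not overlap. None of the drug metabolism genes passed over the list alone or over all genes. The size of this shift rested on control 2, with a median of -0.042 without it (adjusted p = 0.0276), -0.49 without control 1 and -0.18 without knockout 1.

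Small shifts across many members were found for the respiratory chain and the ribosome. Nuclear-encoded oxidative phosphorylation genes were lower in 35 of 38 members (median -0.10, adjusted p = 6.85e-09, and adjusted p = 0.554 with an estimated correlation), and 0 passed over the list alone or over all genes. Cox6c had 420 ± 18.6 and 364 ± 17.4 FPKM and Sdhb 197 ± 0.37 and 172 ± 8.32 FPKM. Knockout 1 did not share the shift, the list level being 0.074 and 0.045 in controls and 0.057, -0.11 and -0.069 in knockouts. The median moved to -0.15 without knockout 1 and to -0.066 without knockout 2. Cytosolic ribosomal protein genes were lower in 45 of 47 members (median -0.077, adjusted p = 1.31e-07, and adjusted p = 0.761 with an estimated correlation), with 0 passing over the list alone or over all genes. Rps29 had 392 ± 21.1 and 333 ± 35.8 FPKM and Rpl14 172 ± 10.9 and 152 ± 10.1 FPKM. Without control 1 the ribosomal median was -0.01 and the call was lost (adjusted p = 0.221), and it was -0.14 without control 2, -0.13 without knockout 1 and -0.03 without knockout 2. With quantile normalization it was -0.047 (adjusted p = 0.0495).

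A further 6 lists were called lower with the preset correlation, each with an adjusted p = 0.517 with an estimated correlation, and 0 members passing over the list alone or over all genes. They were hepatocyte secretory products (median -0.042, 13 of 20 members lower, adjusted p = 0.0124), lipoprotein assembly (median -0.019, 13 of 22 lower, adjusted p = 0.0124), periportal genes (median -0.051, 14 of 22 lower, adjusted p = 0.0304), mitochondrial genome transcripts (median -0.069, 9 of 13 lower, adjusted p = 0.036) and NRF2 targets (median -0.037, 12 of 21 lower, adjusted p = 0.036), besides the female-biased list above. Among secretory genes Ttr had 6234 ± 530 and 5050 ± 218 FPKM, and Serpina3k went the other way, with 5411 ± 1390 and 7311 ± 329 FPKM. Apoc1 had 9567 ± 66.8 and 8400 ± 97.4 FPKM and Etnppl, a periportal gene, 39.4 ± 5.63 and 24.5 ± 4.59 FPKM. ND4L of the mitochondrial genome had 585 ± 26.0 and 436 ± 80.1 FPKM, whereas ND3 had 149 ± 15.5 and 199 ± 43.6 FPKM. Gpx1 had 2768 ± 68.4 and 2279 ± 108 FPKM. The secretory call was lost without control 1 (adjusted p = 0.284), knockout 1 (0.0614) or knockout 3 (0.0627), and its median was -0.080 without control 2. The lipoprotein call was lost without control 1 (median -0.091, adjusted p = 0.0509) or knockout 1 (median -0.028, adjusted p = 0.124). The lipoprotein median was -0.076 without control 2, -0.048 without knockout 2 and -0.0095 without knockout 3. The periportal call was lost without control 2 (median 0.0088, adjusted p = 0.36), knockout 2 (median -0.032, adjusted p = 0.0652) or knockout 3 (0.071), and its median was -0.17 without control 1 and -0.11 without knockout 1. The mitochondrial genome call was lost without control 1 (median -0.12, adjusted p = 0.0596), control 2 (median -0.018, adjusted p = 0.205) or knockout 3 (median -0.037, adjusted p = 0.125), and its median was -0.105 without knockout 1. The NRF2 call was lost without control 2 (median -0.0105, adjusted p = 0.486), knockout 1 (median 0.043, adjusted p = 0.132) or knockout 3 (median 0.019, adjusted p = 0.0735), and its median was -0.12 without control 1 and -0.087 without knockout 2. With quantile normalization these 5 lists and the female-biased list were not called, with adjusted p between 0.0655 and 0.596, nor with no filter on low values, with adjusted p between 0.0768 and 0.118. The female-biased list was not called with filters of 0.1 FPKM (0.109) and 5 FPKM (0.0741). The mitochondrial genome list was not called with these filters (0.0515 and 0.0551) or with length correction (0.219). The NRF2 list was not called at 5 FPKM (0.12) or with length correction (0.0795), nor the periportal list at 5 FPKM (0.0562).

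Erythrocyte transcripts were higher mainly in knockout 1. The 4 distinct hemoglobin rows summed to 73.2 and 75.0 FPKM in controls and to 1235, 168 and 82.1 FPKM in knockouts. All 7 tested members of the list were higher (median 1.68, adjusted p = 0.036, and adjusted p = 0.761 with an estimated correlation), with 0 passing over the list alone or over all genes. Of these 7, Hbb-b1 and Hbb-bs hold the same values. Without knockout 1 the median was 0.52 and the list was not called (adjusted p = 0.0631), nor was it without control 1 (adjusted p = 0.221). On all 5 livers the call was also lost with no filter (median 0.95, adjusted p = 0.0575) and with library weights (median 1.56, adjusted p = 0.0525). Knockout 1 also had the highest level of the 5 livers for Mup genes (0.73) and male-biased genes (0.54) and the lowest for female-biased genes (-0.50), fatty acid oxidation (-0.31) and drug metabolism (-0.21).

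**Figure D2:**
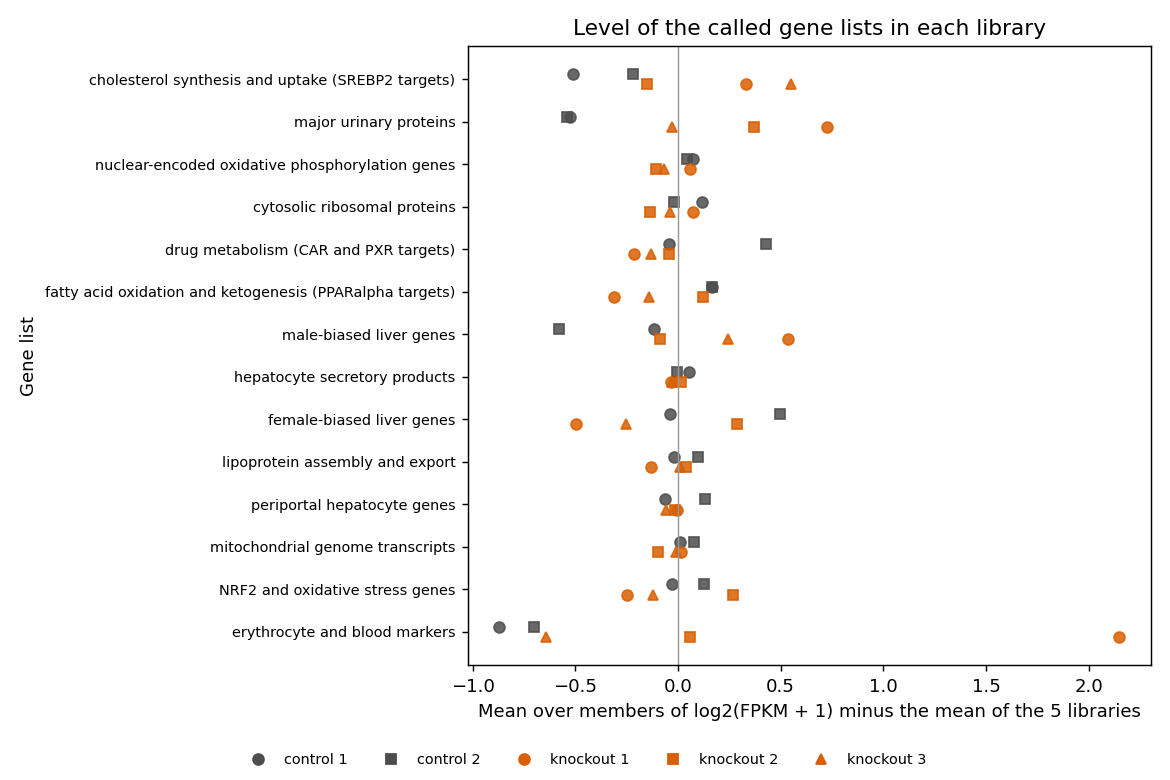
Level of the 14 called lists in each liver, as the mean over members of log2(FPKM + 1) minus the mean of the 5 livers, with controls in grey and knockouts in orange. The levels of the groups do not overlap for cholesterol synthesis, major urinary proteins, male-biased genes, fatty acid oxidation and erythrocyte markers, and knockout 1 stands alone at 2.15 for erythrocyte markers.

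No list for the cells in which Lyve1-Cre acts was called in these whole-liver values, where a change confined to a minority of cells may not show. Only 13 of 21 HEG1-CCM, 7 of 12 lymphatic and 8 of 18 angiocrine members were tested. The HEG1-CCM pathway list (median 0.028, 10 of 13 members higher), sinusoidal endothelium markers (median 0.055, 15 of 22), lymphatic endothelium markers (median 0.053, 4 of 7) and angiocrine factors (median 0.034, 4 of 8) each had an adjusted p of 0.996. Their medians turned negative under quantile normalization and length correction. For the first 3 camera put the list below other genes although median and mean were positive, with 64.2% of all genes higher in knockouts. Leaving out 1 library moved these medians. The HEG1-CCM median was 0.124 without knockout 2, and the sinusoidal median 0.11 without control 1 and 0.0087 without control 2. The lymphatic median was -0.0455 without control 1 and 0.186 without control 2, and the angiocrine median 0.19 without control 1 and -0.041 without control 2. Continuous endothelium markers had a median of 0.21 with 13 of 15 members higher (adjusted p = 0.0652), among them Cav1 (1.12 ± 0.26 and 2.23 ± 0.16 FPKM). They passed with median-of-ratios scaling (0.0271), with length correction (0.0471) and without control 2 (0.0276). Their median was 0.077 with no filter (0.265) and 0.12 with a filter of 0.1 FPKM (0.215), and their adjusted p was 0.381 without control 1. They had an adjusted p = 0.517 with an estimated correlation. Klf2, an endothelial target of the pathway, had 4.28 ± 0.31 and 3.85 ± 0.81 FPKM, with a log2 fold change of -0.13 (95% interval -0.53 to 0.26) that lay between -0.27 and -0.067 when 1 library was left out. Klf4 stood at 0.47 ± 0.042 and 0.44 ± 0.31 FPKM. Of the endothelial Wnt signals, Wnt2 had 1.27 ± 0.32 and 1.21 ± 0.18 FPKM, Wnt9b 0.24 ± 0.092 and 0.18 ± 0.046 FPKM, and Rspo3 0.99 in both controls and 1.26 ± 0.21 FPKM in knockouts. Stab2, a sinusoidal scavenger receptor, had 12.3 ± 0.40 and 13.5 ± 1.02 FPKM, with a 95% interval of -0.15 to 0.38 for the log2 fold change.

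Pericentral genes, which depend on endothelial Wnt, were not called (median 0.055, adjusted p = 0.186), except without knockout 1 (median -0.0797, adjusted p = 0.0291). On all 5 livers they had an adjusted p = 0.805 with an estimated correlation. Their markers Glul (249 ± 23.2 and 259 ± 26.2 FPKM) and Cyp2e1 (3945 ± 842 and 3520 ± 209 FPKM) differed by less than their spread. Lipogenesis genes were not called (adjusted p = 0.885), with 15 of 24 members higher, a positive median (0.10) and mean (0.14), and a place below other genes in camera. Their median was 0.264 without control 2 and 0.223 without knockout 2. Pericentral (mean 0.0036) and lipid droplet genes (mean 0.046) differed in sign between median and camera in the same way. Pklr had 353 ± 37.8 and 249 ± 24.2 FPKM, and the desaturase Fads1 had 91.6 ± 2.99 and 145 ± 28.4 FPKM. Fasn had 86.5 ± 30.1 and 125 ± 53.9 FPKM and Scd1 289 ± 193 and 657 ± 383 FPKM. With 1 library left out the log2 fold change lay between 0.11 and 0.83 for Fasn and between 0.43 and 1.90 for Scd1. Gluconeogenesis and insulin signalling genes were not called (adjusted p = 0.151) and had a positive median (0.043) beside a negative mean (-0.12), G6pc1 alone passing over the list. They were called lower without control 2 (median -0.052, adjusted p = 0.0319), and on all 5 livers had an adjusted p = 0.517 with an estimated correlation. Lipid droplet genes had a median of 0.013 (adjusted p = 0.675), Cd36 16.0 ± 9.77 and 12.3 ± 0.96 FPKM, and the bile acid enzyme Cyp7a1 25.7 ± 1.03 and 42.2 ± 28.4 FPKM.

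Of the non-parenchymal lists, Kupffer cell markers (median 0.23, adjusted p = 0.112), interferon-stimulated genes (median 0.23, adjusted p = 0.0826), MHC class II genes (median 0.27, adjusted p = 0.2), stellate cell markers (median -0.037, mean 0.0093, adjusted p = 0.288) and collagens (median -0.043, adjusted p = 0.0791) were not called. On all 5 livers Kupffer cell markers passed with median-of-ratios scaling (0.0441), quantile normalization (0.034) and length correction (0.042). Interferon-stimulated genes passed with a filter of at least 5 FPKM (0.0365), median-of-ratios scaling (0.0412) and length correction (0.0398). The first 3 lists also depended on which control was kept. Without control 2 their medians were 0.59, 0.43 and 0.63 and all 3 were called higher, though on all 5 livers each had an adjusted p = 0.805 with an estimated correlation. Without control 1 they were -0.11, -0.0048 and -0.14, and MHC class II genes were then called lower (adjusted p = 0.0326). Kupffer cell markers were also called without knockout 1 (0.0336) and interferon-stimulated genes without knockout 3 (0.00811). Collagens were called lower without knockout 2 (median -0.098, adjusted p = 0.0316) and stellate cell markers without knockout 3 (median -0.14, adjusted p = 0.01). On all 5 livers collagens had an adjusted p = 0.517 and stellate cell markers an adjusted p = 0.805 with an estimated correlation. Oasl1, an interferon-stimulated gene, had 6.86 ± 0.13 and 10.1 ± 0.59 FPKM, and Col1a1 1.75 ± 0.65 and 1.24 ± 0.22 FPKM. The 8 lists with fewer than 5 tested members, among them neutrophil, lymphocyte, platelet, adipose and pancreas markers, were not tested with the main filter.

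In all, 14 of 39 lists were called with the preset correlation, 4 higher and 10 lower. With an estimated correlation 0 were called (smallest adjusted p 0.517), and fry called 0 (smallest adjusted p 0.745). Camera's unadjusted p rose with an estimated correlation even where that correlation lay below the preset 0.01. For continuous endothelium markers (-0.0076) it went from 0.0251 to 0.0966, and for collagens (0.0056) from 0.0325 to 0.114. A call lost in this way therefore does not by itself show that correlation between members had made the call. Libraries did not group by genotype over all genes. Pearson correlations of log2(FPKM + 1) across genes were between 0.980 and 0.987, with 0.986 between the controls and 0.987 between control 1 and knockout 1. The first principal component held 31.3% of the variance, with scores of -1.09 and -21.7 in controls and 18.1, -2.59 and 7.25 in knockouts. No library repeated another, since at most 0.425% of tested genes had equal FPKM in any pair.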

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

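The transcript-length correction and the counts of splits for genes were chosen after the result was seen. The count of genes with adjusted p below 0.05 was 0 in each alternative using all 5 livers, 5 with the replicate block, and between 0 and 1 when 1 library was left out. The smallest adjusted p ranged from 0.0076 without control 1 to 0.697. The 10 splits of the 5 libraries are too few for a share under 0.05. With limma the real split gave 0 genes and the highest other 3. All 10 splits reach a count of 0 by construction, so this comparison decides nothing. At an unadjusted p below 0.05 the real split gave 757 genes and the highest other 775. Counting the real split, 2 splits lay at or above the real count. The real split called 14 lists and the highest other 16, with 3 splits at or above the real count, the real split included.

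With limma's replicate block, a paired fit on the replicate number, knockout 3 has no control of its number and adds nothing to the contrast. Fold changes of genes therefore equal those without knockout 3, while p-values differ. List medians differ where the filter on mean FPKM keeps other members. The HEG1-CCM median was -0.0019 with the block and 0.0175 without knockout 3. In this fit 5 genes passed, of which Mup11 and LOC108167922 were chosen after their values were seen. Mup16, Mup9, Moxd1 and Mup11 were higher, and LOC108167922 was lower. The log2 fold changes of Wnt2 (0.017) and Klf4 (0.041) and the medians of the HEG1-CCM (-0.0019) and NRF2 (0.019) lists reversed. Of the lists, periportal (adjusted p = 0.082), mitochondrial genome (0.1) and NRF2 genes (0.0712) were no longer called. Interferon-stimulated (0.00509) and MHC class II genes (0.0458) were called higher and stellate cell markers (0.012) and unfolded protein response genes (1.42e-05) lower. The last list had a median of -0.0825 and an adjusted p of 0.0971 with the main settings. Without the block, each of these newly called lists had an adjusted p = 0.805 with an estimated correlation. Deviations from the group mean correlated across genes at 0.227 and 0.196 in the pairs sharing a number. With 2 controls their deviations are exact opposites, so these values are not 2 separate signs of pairing. The numbers are taken only to name libraries.

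With an estimated correlation 0 lists were called, with fry 0, and with no filter on low values 8. Of these 8, 7 were among the 14 of the preset correlation, and the other, intestine and gallbladder markers (lower, adjusted p = 0.0338), had too few members under the main filter. With mean FPKM of at least 0.1 that list (0.00181, lower) and lymphocyte markers (0.0494, higher) were called. Quantile normalization called 10 lists, 8 of them among the 14. When 1 library was left out between 10 and 16 lists were called, between 8 and 13 of them among the 14. The lists of Mup, cholesterol synthesis, fatty acid oxidation, drug metabolism and oxidative phosphorylation genes were the 5 called in each alternative with the preset correlation. The other 9 of the 14 were called in some alternatives only, and 13 of the 25 lists tested but not called with the main settings were called in at least 1 alternative. Robust limma has no camera result. Heg1 has no value at a mean FPKM of at least 5.

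Reversed values in other alternatives, whose cause was not tested, were as follows. With mean FPKM of at least 0.1 lipid droplet genes had a median of -0.0016, and with at least 5 pericentral genes had -0.062. With median-of-ratios scaling Glul had -0.0094, and the medians were -0.0071 for HEG1-CCM, -0.0074 for sinusoidal, -0.019 for angiocrine, -0.0071 for pericentral, -0.055 for lipid droplet and -0.022 for gluconeogenesis genes. With quantile normalization Heg1 had -0.012, and the medians were -0.024 for HEG1-CCM, -0.01 for sinusoidal, -0.033 for lymphatic, -0.044 for angiocrine and -0.024 for lipid droplet genes. With length correction Heg1 had -0.0405, and the medians were -0.013 for HEG1-CCM, -0.031 for sinusoidal, -0.0799 for lymphatic, -0.031 for angiocrine and -0.049 for lipid droplet genes.

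Leaving out a control leaves 1 control, assumed to vary like the knockouts. Log2 fold changes whose sign then depended on the library left out ranged from -0.0199 to 0.11 for Heg1, -0.17 to 0.11 for Wnt2, -0.036 to 0.15 for Glul, -0.37 to 0.0696 for Cyp2e1, -0.85 to 0.40 for Cd36, -0.096 to 1.09 for Cyp7a1, -0.51 to 0.10 for Lyve1, -0.60 to 7.52 for Hamp, -0.35 to 4.32 for Hamp2, -0.22 to 0.041 for Klf4 and -0.14 to 0.012 for Wnt9b. List medians ranged from -0.0455 to 0.19 for lymphatic, -0.041 to 0.19 for angiocrine, -0.11 to 0.59 for Kupffer, -0.14 to 0.63 for MHC class II, -0.0048 to 0.43 for interferon-stimulated, -0.14 to 0.097 for stellate, -0.0797 to 0.13 for pericentral, -0.17 to 0.0088 for periportal, -0.064 to 0.078 for lipid droplet, -0.061 to 0.056 for gluconeogenesis, -0.12 to 0.043 for NRF2, -0.032 to 0.24 for BMP and iron, -0.17 to 0.12 for unfolded protein response genes, and -0.45 to 0.036 for female-biased genes.

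Of 1466 pairs of a named gene and an alternative, over 78 genes with Heg1, 1441 kept their direction and side of the threshold, 6 newly passed (the block and Hamp without control 1) and 19 reversed. In 67 of the 78 genes no alternative reversed, and 11 had at least 1 that did. Much of this tally was fixed in advance, so it is no measure of how stable the genes are. None of the named genes passed with the main settings, so none could lose a pass. The other table held identical values, so its pairs could not differ. Genes taken because their groups do not overlap cannot reverse when 1 library is left out. Depth is unknown, so what depth limits was not tested.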

Other observations

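The test of other splits for the cholesterol list, the test of flanking DNA at Lyve1 alone and the transcript-length correction were chosen after the result was seen. Hepcidin stood apart in control 2, and Hamp and Hamp2 were chosen after their values were seen. Hamp, the iron-regulating hormone induced by BMP signalling, had 1809 and 5.53 FPKM in controls and 1082, 1673 and 943 FPKM in knockouts. Its paralog Hamp2 had 297 and 10.7 FPKM in controls and 284, 165 and 268 FPKM in knockouts. The list of BMP and iron genes had a median log2 fold change of 0.10, a mean of 0.40 and an adjusted p of 0.634, and its level was -0.57 in control 2. Id3, a target of BMP signalling, had 12.8 ± 2.98 FPKM in controls and 20.7 ± 1.42 FPKM in knockouts. Without control 2 the median of the list was -0.032, and without control 1 it was 0.24 (adjusted p = 0.0369), while on all 5 livers the list had an adjusted p = 0.83 with an estimated correlation.

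Oxidative phosphorylation and ribosomal protein genes, both short and abundant, were slightly lower in knockout livers. A trend with transcript length as the whole cause is argued against, since both medians lay at percentile 0.02 of 10000 length-matched lists and were -0.12 and -0.11 after length correction. The median of all genes was 0.061 with the main settings and 0.0026 after that correction. Measured against all genes, both shifts were therefore smaller after it, and length may account for a part. A few abundant genes taking a different share of the FPKM is argued against as the whole cause too. Median-of-ratios scaling moved the medians from -0.10 to -0.168 (bootstrap SE over members 0.011) and from -0.077 to -0.145 (0.012). It also moved the median of all genes from 0.061 to 0.0026, so against all genes both shifts changed little. Members correlated (estimated at 0.597 and 0.801), and neither this SE nor the percentile measures the spread between livers. Quantile normalization brought the medians to -0.078 (preset-correlation adjusted p = 0.000662) and -0.047 (adjusted p = 0.0495). The median of all genes was then -0.0021, so against all genes this scaling made both shifts clearly smaller. For chance the 10 splits are too few for a share under 0.05. Oxidative phosphorylation had -0.10 in the real split against -0.107 and 0.157 in others (3 splits as far from 0, the real split included). Ribosomal genes had -0.077 against -0.155, 0.12 and 0.136 (4 splits, the real split included). Under the prediction written beforehand, so many splits go with chance for both lists. Chance, a difference between the genotypes or a difference in the handling of the livers may lie behind both, and the choice between them stays open.

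Lower Cyp4a14 with higher cholesterol synthesis genes could arise from a difference in time of day at collection. This stays open, the clock genes' median absolute change of 0.14 lying at percentile 80 of 10000 lists matched for expression. The 10 splits are too few for a share under 0.05. The cholesterol median was 0.54 in the real split and -0.65 in the highest other, which sets knockouts 1 and 3 apart. Counting the real split, 2 splits lay as far from 0. An effect of the genotype remains a hypothesis.

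Flanking DNA carried along with the Lyve1-Cre allele alone could place the genes with the smallest p near Lyve1. Of the 100 genes with the smallest p, 3 lay within 20 Mb of Lyve1 or Heg1, against 4.06 expected (one-sided Fisher's exact p = 0.778). Per the labels both groups carry the floxed Heg1 allele, and 0 of the 100 lay near Lyve1, against 2.25 expected. This argues against flanking DNA of the Lyve1-Cre allele as the source of most of these genes, provided that the Cre lies at Lyve1, which the labels do not state.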
